A study of Homo sapiens with 5 samples.

How the data were processed

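FAIRE-seq libraries of 2 untreated and 2 PMA-treated MCF-7 cultures were analysed, with 1 mixed total input as their common background. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 min, the chromatin was sonicated, free DNA was extracted with phenol-chloroform, and 20 ng of it went into each library. Replicates are biological per the series' design text. Groups and replicate numbers came from the sample titles.

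Each FAIRE library came as 1 deposited list of islands without a header. Per the submitters' processing notes, the build was hg19 and the tools included cutadapt, Bowtie2, Picard, HTSeq and SICER; their versions and settings are not given in the sources used here. The names of the deposited lists state removed duplicates, a window of 100 bp, a gap of 100 bp and an FDR of 0.01. The deposited lists give for every island a raw FAIRE read count and a raw input read count, neither of them normalized by the authors. They also give a deposited p-value, a fold ratio over input and an FDR as the authors' adjusted p-value. The meaning of these columns was settled from the values: the fold equals FAIRE reads over input reads times 1 constant per library, with an input of 0 taken as 0.25, and the p-value is a Poisson tail, both recomputed for 100% of the islands within a relative 1e-06. That constant is the library size relative to the input, 0.340 and 0.355 for the untreated and 0.611 and 0.663 for the PMA libraries. The authors called islands in each library separately, so a fold or p-value belongs to its own island, and only islands past the FDR are listed. The count of a region that a library does not list is therefore unknown. Intervals listed by more than 1 library, 20236 of them, had the same input count in each list. Total mapped reads are not given in the sources used here. Depth is given as reads in islands, and an island had a median of 20 and 22 reads in the untreated and 33 and 38 in the PMA libraries. The input's own reads were not analysed here beyond these counts.

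Islands of the 4 lists were merged into regions where they overlapped by at least 1 bp, and a region was called in a library that listed an island in it. Positions are 1-based. Condition-specific regions were called in both libraries of one condition and in neither of the other. The distance to a chromosome end was taken from position 1 and from the end of the last island listed on the chromosome, since chromosome lengths of the build were not used here. No p was computed for their number, since 4 libraries can be split into pairs in only 3 ways. To see whether absence could come from library size, the reads of each such region were rescaled to each library of the other condition, by library size relative to the input, and tested with a Poisson test against the same input reads at the largest p that library listed. The interval of a fold based on 1 or 2 input reads is the exact Clopper-Pearson 95% interval of the FAIRE share of the reads, and a fold over 0 input reads is bounded with a floor of 3 input reads per region. Reads are not independent molecules, so intervals and floors cover counting error only.

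In regions called in all 4 libraries, reads of all islands of a region were summed per library and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM, Benjamini-Hochberg, threshold 0.05) in R 4.3.3, with untreated and PMA libraries only and no covariate. Such a sum grows with the length called in that library, so the covered length and the fold stand beside it. limma 3.58.1 and DESeq2 1.42.0 served as alternatives. Other values were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and plots with matplotlib 3.10.9. The edgeR step was tested on simulated counts for the same 29445 regions with 200 changed ones. It recovered 39% of the regions changed by 1 and 92% of those changed by 2 on the log2 scale, and 7.09% of its calls were false. The simulation drew counts without island calling and changed far fewer regions than the 8382 that passed in the data. Its rates therefore leave out any error from the called length and do not describe the calls in the data. The merging and classes were tested on 20000 simulated loci, and 100% of the patterns of calls came back with the right number of regions. Islands of a simulated locus always overlapped and loci lay apart, so this checked the code only. Broken stretches and chains of islands, as real lists can hold, were not simulated.

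Tests, alternatives and the rule for named regions were fixed before the data were examined. The rule took the 10 PMA-specific and 10 untreated-specific regions with the largest fold, by the lower of the replicates, and the 10 higher and 10 lower regions with the largest change at an adjusted p under 0.05 in the read count test, with a mean of at least 50 reads and no overlap of the groups. The alternatives were a stricter FDR of 1e-05, a fold of at least 2, equal numbers of islands, joining over 500 bp, sharing of 50% of the shorter island, a width of at least 300 bp, other library sizes and tests, read count filters, a replicate block, each replicate left out in turn, and leaving out chromosomes 1, 3, 17 and 20, where MCF-7 is known to carry amplified segments. Gene annotation and sequence of hg19 were not used here, and the gene table at hand belongs to another assembly, GRCh38.p14. Gene names, promoter shares, gene lists and sequence motifs were therefore not analysed here.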

Results

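Chromatin accessibility was measured by FAIRE-seq in MCF-7 cells, an estrogen receptor-positive human breast cancer line with an epithelial phenotype. FAIRE recovers DNA fragments that are not held in nucleosomes by phenol-chloroform extraction of formaldehyde-fixed, sonicated chromatin, and the fragments are then sequenced. The cells were left untreated or were stimulated for 60 h with 1.3 ng/ml PMA (phorbol 12-myristate 13-acetate), an activator of protein kinase C. The series concerns accessible chromatin in the epithelial to mesenchymal transition and in the formation of breast cancer stem cells, and its design states 2 biological replicates per condition. One mixed total input served as background for all 4 FAIRE libraries. Each library was represented by a list of islands, which are stretches of the hg19 genome where FAIRE reads exceeded the input, each with its FAIRE read count, its input read count and its fold over input. The reads in islands numbered 5357909 and 6816804 for untreated replicates 1 and 2, and 4454351 and 5893469 for PMA replicates 1 and 2. Regions are given by position only, since no annotation of this build was used here.

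Listed islands were fewer, and their fold over input was lower, in the libraries of PMA-treated cells. Untreated cells had 133492 ± 10418 islands (mean ± SD, n = 2) covering 90.1 ± 9.6 Mb, and PMA-treated cells had 73070 ± 1030 islands (n = 2) covering 52.6 ± 6.6 Mb, a ratio of 0.547 for the numbers. The median fold over input of the listed islands was 3.69 ± 0.10 in untreated and 2.69 ± 0.12 in PMA-treated cells (n = 2 each). A fold of at least 4 was reached by 45.1 ± 1.3% of the islands of untreated cells and by 23.6 ± 2.2% of those of PMA-treated cells. These folds cover only islands that passed a test on read counts, and a smaller library needs a higher fold to pass. The untreated libraries were the smaller ones, so part of these fold differences may come from library size, which was not tested. Mitochondrial DNA, which is not packed in nucleosomes, formed 1 island of 16500 bp in every library, with a fold of 4.73 ± 0.10 in untreated and 2.84 ± 0.13 in PMA-treated cells. Duplicates had been removed, which caps the reads that a stretch of this length can hold. The median island was 500 bp wide in 3 libraries and 600 bp wide in PMA replicate 2. The PMA libraries were the larger ones, with a size relative to the input of 0.637 ± 0.037 against 0.348 ± 0.010 in untreated cells. With 2 libraries against 2, a two-sided exact permutation test cannot give a p below 0.333, so each of these differences is given with the spread of its replicates only, and no PMA library overlapped an untreated one in number of islands, median fold or library size.

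**Figure D1:**
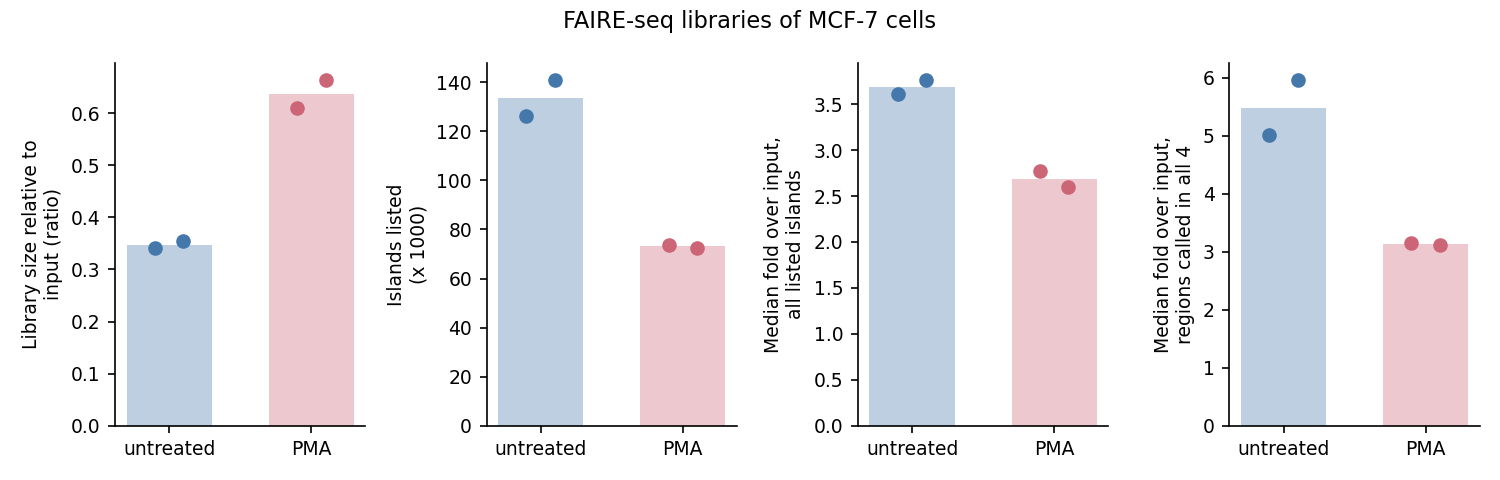
Library size relative to the input, number of listed islands (axis in units of 1000), median fold over input of all listed islands, and median fold over input in regions called in all 4 libraries. Points are the 2 libraries of a group and bars are their mean. The PMA libraries were larger (0.611 and 0.663 against 0.340 and 0.355) and had fewer islands and lower fold.

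Libraries of the same condition shared more of their accessible sequence than libraries of different conditions. The base-pair Jaccard index was 41.0% between the untreated replicates and 40.1% between the PMA replicates, and 17.6 to 24.7% for the 4 pairs of an untreated with a PMA library. Merging the 4 lists gave 216918 regions, of which 29445 were called in all 4 libraries. In untreated cells, 36618 regions were called in both replicates and in neither PMA library (untreated-specific), and 13569 were called in both PMA replicates and in neither untreated library (PMA-specific). These 50187 regions compare with 2726 and 2310 for the other 2 ways of splitting the 4 libraries into pairs. The PMA-specific regions covered a median of 450 bp with a median fold of 2.93, and the untreated-specific regions a median of 550 bp with a median fold of 3.12.

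**Figure D2:**
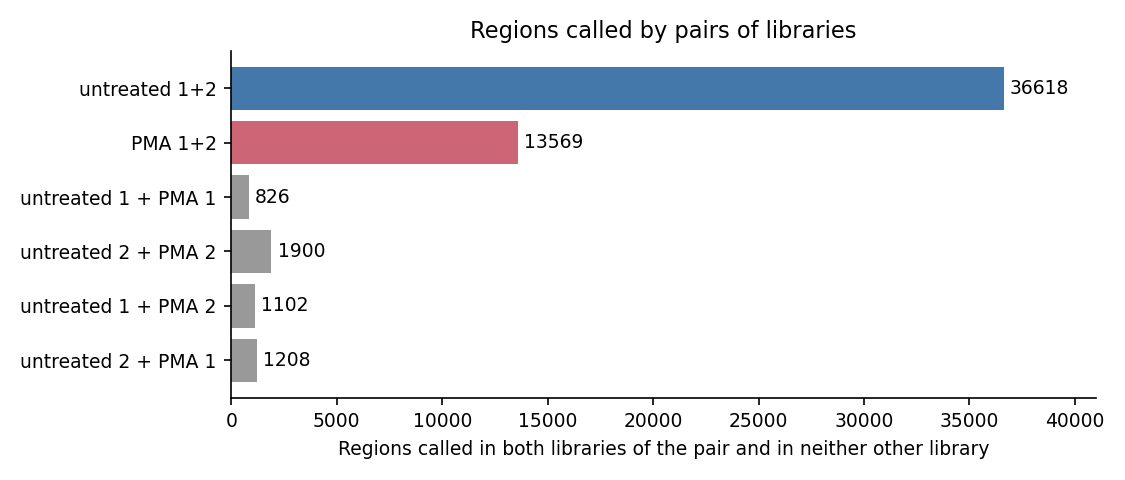
Number of regions called in both libraries of a pair and in neither of the other libraries, for the 6 pairs of the 4 libraries. The pairs of one condition gave 36618 and 13569 regions, and the 4 mixed pairs gave 826 to 1900.

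Untreated-specific regions made up 73.0% of the condition-specific regions when every listed island was used, and this direction turned when lists of equal length were compared. With the 72342 islands of highest fold in each library, 11453 regions were untreated-specific and 19639 PMA-specific, which put the untreated-specific share at 36.8%. This cut kept all islands of PMA replicate 2 and nearly all of the 73798 of PMA replicate 1. It left out many of the 126125 and 140858 islands of untreated replicates 1 and 2. A region whose untreated islands fell below the cut then counted as PMA-specific, so part of the turn was built in. Scaled by library size relative to the input, the reads of 10621 PMA-specific regions (78.3%) would have passed in both untreated libraries. Scaled by the reads in regions called in all 4 libraries, those of 7905 untreated-specific regions (21.6%) would have passed in both PMA libraries. The opposite directions scale the reads up relative to the test, so that a pass was built in and they show nothing. Leaving out untreated replicate 1 or 2 raised the untreated-specific regions to 88432 or 74282, and leaving out PMA replicate 1 or 2 raised the PMA-specific regions to 25441 or 31071, since 1 library then sufficed for the call.

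The PMA-specific regions with the largest fold over input were short, between 100 and 400 bp, and lay on chromosomes 1, 4, 6, 8, 9, 12 and 22. The region at chr4:74519401-74519700 had 20 and 26 reads in PMA replicates 1 and 2 against 1 input read, a fold of 32.8 (95% exact interval 5.24 to 1358) and 39.2 (6.44 to 1607). At chr12:72240201-72240400 the fold was 39.3 (6.41 to 1616) and 27.1 (4.28 to 1131), and at chr9:72651701-72651900 it was 29.5 (4.65 to 1228) and 27.1 (4.28 to 1131). Also among the 10 were a pair of regions on chromosome 6, chr6:28693701-28693900 with 16 and 22 reads and chr6:28775501-28775700 with 18 and 16 reads. These intervals cover counting error only, and the input held 1 or 2 reads in each of the 10 regions. Among PMA-specific regions with at least 10 input reads, a set chosen after the values were seen, the largest fold was 8.71 ± 0.51 (n = 2) at chr12:113652701-113653200, followed by 7.73 ± 0.77 at chr7:98759901-98760600. The 10 regions of that set ranged from 6.84 to 8.71 in mean fold.

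The 10 untreated-specific regions with the largest listed fold had no input reads, so their fold can only be bounded. Against a floor of 3 input reads per region, which leaves out the counting error of the FAIRE reads, chr6:16711801-16712100 was at least 14.7-fold and at least 20.7-fold enriched in untreated replicates 1 and 2, with 15 and 22 reads. With that error included, the exact 95% lower limits were 10.5 and 15.4. The regions chr2:90381001-90381500, with 15 reads in each replicate, and chr9:129317801-129318200, with 15 and 14 reads, were at least 14.1-fold and at least 13.2-fold enriched in both replicates, with exact lower limits of 10.5 and 10.1 for the former and 10.5 and 9.35 for the latter. Among the 10, the lowest value against the floor was 8.81 and the lowest exact limit 5.80. Among untreated-specific regions with at least 10 input reads, chosen after the values were seen, chr6:1737701-1738500 had the largest fold, 12.9 ± 1.0 (n = 2), followed by chr7:152611001-152612200 at 11.4 ± 1.1 and chr16:87255201-87256200 at 10.99 ± 0.12.

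Condition-specific regions were unevenly spread over the chromosomes. With every listed island, untreated-specific regions made up 89.7% of the condition-specific regions on chromosome 19, 88.5% on chromosome 16, 87.1% on chromosome 20, 86.8% on chromosome 17 and 85.2% on chromosome 21. The share was lowest on chromosome 6, where 567 untreated-specific regions stood against 727 PMA-specific ones (43.8%), and on chromosome X, with 302 against 312 (49.2%). Chromosomes 18 and 4 followed with 56.0% and 56.3%. With the 72342 islands of highest fold in each library, an alternative chosen here after seeing the data, the share was below 50% on 21 of 23 chromosomes and above it on chromosomes 19 (67.0%) and 17 (56.5%). That cut removed almost only untreated islands, so part of the fall was built in, here and in the windows below. It was then 48.1% on chromosome 16, 41.5% on chromosome 20, 34.9% on chromosome 21 and lowest on chromosome 6 (21.8%). Of the islands of a library, 4.14 ± 0.04% lay on chromosome 6 in PMA-treated and 2.57 ± 0.09% in untreated cells, and 4.74 ± 0.35% against 6.79 ± 0.27% lay on chromosome 16 (n = 2 each). With equal numbers these shares were 4.18 ± 0.09% against 3.41 ± 0.17% and 4.75 ± 0.34% against 5.61 ± 0.18%. The share of islands was higher in both PMA libraries than in both untreated ones on 10 of 23 chromosomes and lower on 9, and on 11 and 8 with equal numbers. The 1-Mb window with most PMA-specific regions was chr5:73000001-74000000, with 34 PMA-specific and 4 untreated-specific regions. The window with most untreated-specific regions was chr17:57000001-58000000, with 186 against 6, followed by chr7:1000001-2000000 with 171 against 1 and chr9:139000001-140000000 with 171 against 0. With equal numbers the windows held 38 PMA-specific against 1 untreated-specific region on chromosome 5, and 60 untreated-specific against 12 PMA-specific, 21 against 17 and 23 against 10 in the other named windows.

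Untreated-specific regions lay near chromosome ends more often than PMA-specific regions. Within 5 Mb of an end were 24.7% of the untreated-specific, 5.45% of the PMA-specific and 14.8% of the regions called in all 4 libraries. The share was higher for untreated-specific than for PMA-specific regions on 22 of 23 chromosomes, the exception being chromosome 15 with 5.50% against 10.6%. Of all listed islands, 19.5% and 19.7% lay there in the untreated libraries and 10.98% and 12.6% in the PMA libraries. The ratio of 4.54 between the classes was 1.77 when the 72342 islands of highest fold were compared.

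**Figure D3:**
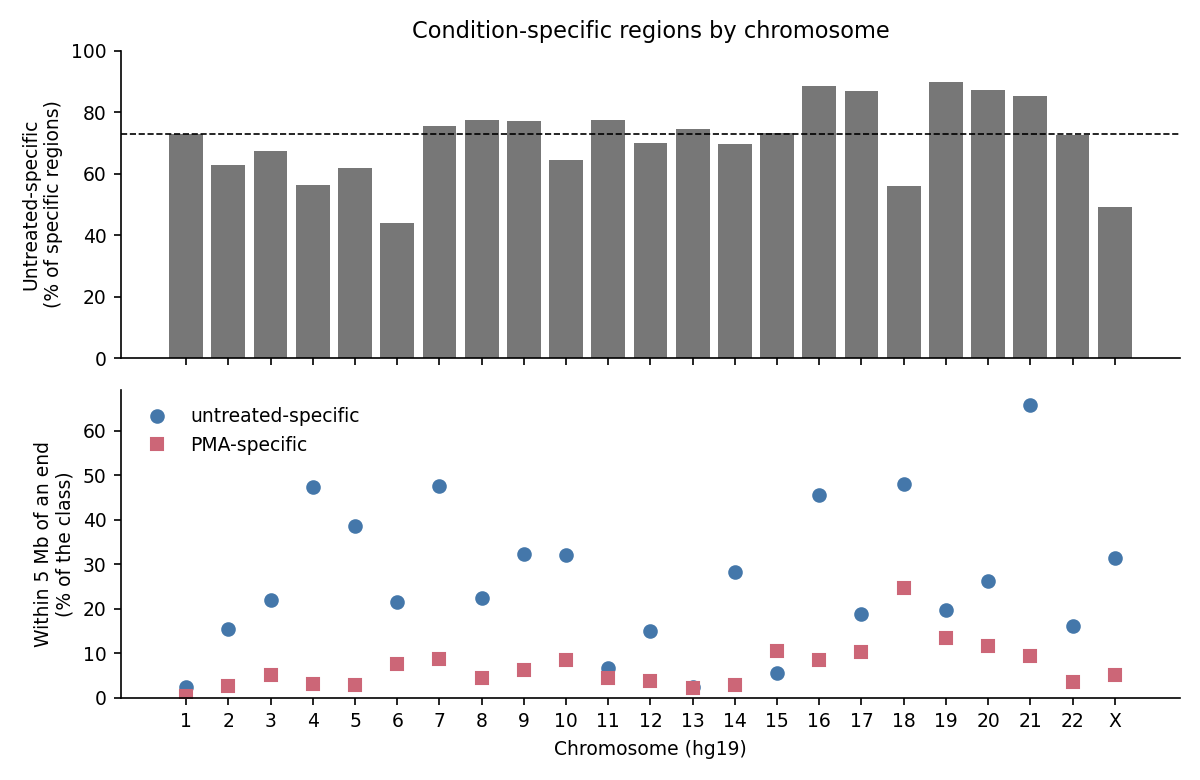
Upper panel, untreated-specific regions as a percent of the condition-specific regions of each chromosome, from every listed island, with the genome-wide value of 73.0% as a dashed line. Lower panel, percent of untreated-specific (circles) and PMA-specific (squares) regions of each chromosome within 5 Mb of an end, higher for untreated-specific regions on 22 of 23 chromosomes.

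In the 29445 regions called in all 4 libraries, enrichment over input was lower after PMA. The median fold was 5.01 and 5.95 in the untreated libraries and 3.15 and 3.11 in the PMA libraries. The excess of the fold over 1 had a median PMA to untreated ratio of 0.464. When read counts were centred on these regions by TMM, 4977 regions were higher and 3405 lower with PMA at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg over 29445 regions, n = 2 per group), with a median log2 change of 1.38 and -0.83. When the same counts were scaled by library size relative to the input, the median region fell by 0.98 on the log2 scale, and 974 regions were higher and 16646 lower. The lower share of the calls was thus 40.6% with TMM and 94.5% with input scaling. It was 29.5% with DESeq2, 23.8% with total reads in islands as library size, 52.2% per covered base and 99.4% with limma on the log2 fold over input. These totals do not stand for the same regions. Per covered base, 544 of the higher and 195 of the lower TMM calls kept their call, and 201 were called in the opposite direction. With limma on the log2 fold these numbers were 26, 1849 and 1009. With input scaling, 972 and 3405 kept their call and 0 turned, and with DESeq2 2910 and 1218 did and 0 turned. With limma on the fold centred on the median region, an alternative chosen after the data were seen, 0 regions were higher and 0 lower at an adjusted p under 0.05, and 3820 were higher and 2947 lower at an unadjusted p under 0.05. The counts of calls were lower when an untreated library was left out, with 2069 higher and 563 lower regions without untreated replicate 1, and 567 higher and 202 lower without untreated replicate 2.

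**Figure D4:**
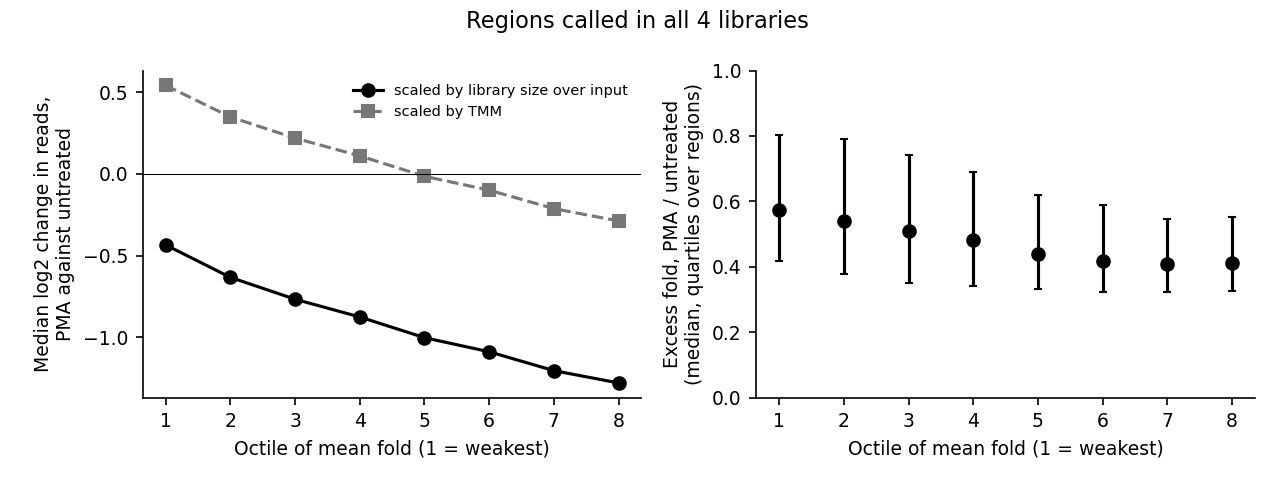
Regions called in all 4 libraries in 8 classes of mean fold over input. The left panel gives the median log2 change in reads with PMA, scaled by library size over input (circles, -0.43 to -1.28) or by TMM (squares, 0.54 to -0.29), and the right panel the median and quartiles over regions of the PMA to untreated ratio of excess fold, with medians between 0.409 and 0.573.

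The regions with the largest TMM-scaled change were those where islands widened or shrank. At chr1:117688301-117694500 the reads in called islands rose by a log2 change of 4.18 (SE 0.29, adjusted p = 0.000356 by edgeR). Those islands covered 600 and 300 bp in the untreated libraries and 5100 and 5500 bp in the PMA libraries. Their fold over input was 3.75 ± 2.18 and 1.37 ± 0.09 (n = 2 each). Reads outside the called islands are not listed, so the change, its p and the folds compare unlike stretches, not the same interval. This also holds for the other regions named in this paragraph. Chromosome 13 gave 3 of the 10 largest increases, chr13:44731801-44735800 with a log2 change of 3.63, chr13:41026201-41028900 with 3.50 and chr13:41076301-41079000 with 3.34. Their fold over input went from 3.52 ± 1.56 to 1.80 ± 0.29, from 5.65 ± 1.35 to 1.71 ± 0.10 and from 3.04 ± 1.75 to 2.96 ± 0.59, while the log2 fold fell by 0.80 in the median region. Relative to the median region, these are log2 changes of -0.10, -0.90 and 0.88. The largest decrease was at chr21:46892401-46903800, with a log2 change of -3.83 (SE 0.26, adjusted p = 0.000356 by edgeR) and a covered length of 9900 and 10900 bp in untreated against 700 and 400 bp in PMA-treated cells. Decreases also included chr16:1475401-1485500 with -3.17, chr20:57414001-57417300 with -3.09 and chr2:133026101-133030400 with -3.02. At the last of these the fold over input was 7.79 ± 0.20 in untreated and 19.3 ± 3.9 in PMA-treated cells, opposite to the reads. The untreated fold was taken over 3700 and 3500 bp and the PMA fold over 200 and 300 bp, so they show no rise over the same interval. With limma on the log2 fold centred on the median region, 4 of the 10 named increases turned to decreases and all 10 named decreases turned to increases, none of them at an adjusted p under 0.05. Per covered base, 9 of the decreases turned and none of the increases. Fold and reads per covered base were also taken over islands of unlike length, so a turned sign does not give the direction over the same interval. Over all 29445 regions, the log2 change in reads and in covered length had a correlation of 0.795, across regions, which are not independent replicates.

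Where the covered length differed by at most 1.5 times between libraries, 1272 of 6742 regions rose and 985 fell with PMA by an edgeR test with TMM refitted on these regions alone, with a median log2 change of 0.89 and -0.43. Of these, 571 and 464 were also called in the fit to all 29445 regions. Input scaling gave 35 higher and 5012 lower in the set. The largest increases in this set, which were named after the values were seen, were at chr1:183423301-183424200 (log2 change 2.21, SE 0.25), with a fold over input of 2.75 ± 0.11 in untreated and 7.002 ± 0.006 in PMA-treated cells (n = 2 each), and at chr20:24015201-24015900, with 3.97 ± 1.08 and 6.79 ± 0.17. At chr2:220586901-220587500 the fold was 3.76 ± 0.48 and 5.66 ± 0.06. These 3 regions were also higher with input scaling, by 1.17, 1.09 and 0.97 on the log2 scale. The largest decrease was at chr12:122109801-122111500, by a log2 change of -1.05 (SE 0.14), where the fold went from 7.96 ± 1.85 to 2.47 ± 0.07. At chr19:14516701-14517300 it went from 12.5 ± 1.0 to 3.50 ± 0.92, with a log2 change of -0.86.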

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

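The test on islands within 50 kb was chosen after the test up to 1 Mb had failed and after the input density by distance had been seen. Islands of at least 20 kb stood out for their number of input reads per kb, a measure that was not itself compared between conditions. The 4 lists held 227 such islands, 207 of them on chromosomes 3, 17 and 20, with a median of 355 input reads per kb there. The widest were chr17:59439001-59629300 in untreated replicate 1 (190.3 kb, fold 1.51), chr3:64531501-64717700 in PMA replicate 2 (186.2 kb, fold 1.04) and chr20:52485801-52650600 in untreated replicate 1 (164.8 kb, fold 1.07). Over all wide islands the median fold was 1.16. They held 9.98% and 5.59% of the reads in islands of the untreated and 11.8% and 19.7% of those of the PMA libraries. On chromosome 3, islands of at least 20 kb were listed only in PMA replicates 1 and 2 (8 and 19), with median folds of 1.09 and 1.06. The widest island there was 12 kb in untreated replicate 1 and 15.2 kb in untreated replicate 2.

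A technical explanation for these islands is a gained copy number of the segments in MCF-7, which raises FAIRE and input reads together and lets a fold near 1 pass a test on counts. Their own input density, against a median of 40 reads per kb over all islands, is what drew attention to them and cannot test this. For a gain that reaches up to 1 Mb from them, 7605 other islands of at most 1 kb there were tested. Their median input density was only 1.25 times that of such islands elsewhere, short of what was predicted for such a gain. High counts can join into wider islands, so short islands may miss the gained parts, and this cannot decide on a broad gain. The next comparison used wider islands, so width and distance are mixed between these tests. Within 20 to 50 kb, 254 other islands of 1 to 20 kb had 2.86 times the input density of islands of that width elsewhere, which is consistent with a gain close to the wide islands, as a hypothesis found and tested on the same data. A change in copy number between the conditions was not tested, since the input was a mixture of both.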

How the results depend on the processing

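The comparisons of equal numbers by p, of reads per covered base with library sizes from the fold column, and of the centred fold in limma, for counts and named regions, and all alternatives for the ratio near chromosome ends, for chromosomes and for windows, were chosen after seeing the data. The share of untreated-specific regions stayed between 70.6% and 77.9% with a fold of at least 2, joining over 500 bp, 50% sharing, a width of at least 300 bp, an FDR of 1e-05 and without chromosomes 1, 3, 17 and 20. An FDR of 1e-05 lowered the counts to 21791 untreated-specific and 8349 PMA-specific regions, since fewer islands entered. With equal numbers of islands the share turned to 36.8% (11453 untreated-specific, 72342 islands by fold), 29.7% (4277, 36171 islands by fold), 39.4% (12165, 72342 islands by p) and 38.6% (5430 against 8630, 36171 islands by p). Equal numbers also moved the Jaccard index to 37.2% within untreated and 35.4% within PMA libraries, and the ratio of shares near chromosome ends to 1.77. They turned the share of windows with more untreated-specific regions, among windows with more of either class, from 71.1% to 22.7%. The share of untreated-specific regions turned to 39.3, 26.2, 30.9, 28.0, 27.8, 37.0, 45.1, 34.6, 31.5, 38.8, 39.5, 44.5, 30.4, 35.8 and 48.1% on chromosomes 1, 2, 3, 4, 5, 7, 8, 9, 10, 11, 12, 13, 14, 15 and 16, and to 32.5, 41.5, 34.9 and 45.6% on chromosomes 18, 20, 21 and 22. It kept its side on chromosomes 6, 17, 19 and X. At 72342 islands the cut removed listed islands almost only from the untreated libraries, so part of these turns was built in. Any other cause was not tested. Without each replicate in turn, untreated-specific regions numbered 39120 to 88432, PMA-specific regions 15402 to 31071 and the share 57.9% to 85.2%, because 1 library then makes the call. A width of at least 300 bp kept the class of 2 of the 10 PMA-specific and 3 of the 10 untreated-specific regions named by fold, since the others hold shorter islands. Library size from the reads in regions called in all 4 left 7905 untreated-specific regions detectable, where the main scaling had a pass of all of them built in.

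The counts of regions that passed in all 4 libraries depended on the scaling. DESeq2 gave 2923 higher and 1225 lower (29.5% lower), library sizes from the fold column 974 and 16646 (94.5%), total reads in islands 2025 lower (23.8%), reads per covered base 1241 and 1355 (52.2%), covered length with library sizes from the fold column 81 and 15328 (99.5%), and limma on the log2 fold 82 and 14090 (99.4%). Between the TMM and the input scaling, the log2 change shifted by -0.98. Why the share also moved per covered base was not tested. Centred on the median region, limma gave 0 higher and 0 lower at an adjusted p under 0.05 (smallest adjusted p 0.0951) and 3820 higher and 2947 lower at an unadjusted p under 0.05. A like covered length gave 1272 higher and 985 lower among 6742 regions, and a mean of at least 50 reads 2909 and 1409 among 17948 regions, with fewer regions tested. Without each replicate in turn, where the lone library is assumed to vary like the other group, 567 to 4846 were higher, 202 to 4644 lower and 21.4% to 48.9% of the calls lower. The edgeR filter on low counts removed 0 regions, so it tested nothing. A replicate block gave 5296 higher and 3567 lower. The labels do not say whether same-numbered libraries shared a culture or day. The deviations of same-numbered libraries had a correlation of 0.0687 across regions. This cannot settle the question, since the read sums follow the length called in each library.

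For the 20 regions named by the size of their read change, 82 of 140 values under other settings kept direction and threshold, 22 kept direction only and 36 turned. With a replicate left out, all 80 values kept their direction. That was largely built in, since the regions were picked from the same libraries as the largest changes without overlap of the groups. The turned values came from reads per covered base, which divides by the covered length, and from limma on the log2 fold with and without centring, which changes the test as well, so that the cause was not tested. In these regions both measures come from islands of unlike length, so a turned value does not give the direction over the same interval. Without centring, the log2 fold fell by 0.80 in the median region, so a turned increase within that fall is no reversal relative to the other regions, and the count of turned values includes them. Per covered base none of the 10 increases turned, and 8 of them no longer passed. With uncentred limma, the increases turned to a log2 change of -1.32 (chr1:117688301-117694500), -0.90 (chr13:44731801-44735800), -0.93 (chr1:144936301-144945300), -1.71 (chr13:41026201-41028900), -0.76 (chr2:190406101-190408200), -0.50 (chr8:127445301-127447600), -0.69 (chr3:192624601-192626700), -0.64 (chr8:124591101-124594100) and -0.22 (chr4:41320601-41322200). Decreases turned to 1.30 (chr2:133026101-133030400), 0.99 (chr9:95869401-95877400), 0.27 (chr16:87725701-87731300) and 0.058 (chr9:139914201-139919000). Centred on the median region, 4 increases turned, to -0.51 (chr1:117688301-117694500), -0.10 (chr13:44731801-44735800), -0.12 (chr1:144936301-144945300) and -0.90 (chr13:41026201-41028900). All 10 decreases turned when centred, to 0.31 (chr21:46892401-46903800), 0.65 (chr16:1475401-1485500), 0.51 (chr20:57414001-57417300), 2.10 (chr2:133026101-133030400), 0.31 (chr20:62183601-62189100), 1.80 (chr9:95869401-95877400), 1.07 (chr16:87725701-87731300), 0.34 (chr8:145538901-145543700), 0.86 (chr9:139914201-139919000) and 0.67 (chr16:67477601-67482100). Per covered base, decreases turned to 0.21 (chr21:46892401-46903800), 0.71 (chr16:1475401-1485500), 0.66 (chr2:133026101-133030400), 0.17 (chr20:62183601-62189100), 1.18 (chr9:95869401-95877400), 0.55 (chr16:87725701-87731300), 0.35 (chr8:145538901-145543700), 0.52 (chr9:139914201-139919000) and 0.63 (chr16:67477601-67482100). Alternatives for gene lists, genomic location and sequence motifs were not run, since no annotation or sequence of the build was used here. Lists that hold only islands past an FDR limit what absence from a list can show.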

Other observations

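The tests on library size, on mitochondrial DNA, on the detectable PMA-specific regions and on the length of the lists were chosen after the results were seen. Condition-specific regions came in runs along the chromosomes. Of 50163 pairs of neighbouring condition-specific regions, 75.1% were of the same class, against a mean of 62.7% and a highest value of 63.3% in 1000 permutations of the classes within chromosomes. Neighbours may be parts of 1 stretch broken into several islands, which the permutations treated as separate regions. Joining over 500 bp left 28841 untreated-specific and 12018 PMA-specific regions, and the runs were not tested again on these. Of 1292 windows of 1 Mb with at least 10 condition-specific regions, 891 held more untreated-specific and 362 more PMA-specific regions, and in 217 the PMA-specific regions were at least 2 times as many. With the 72342 islands of highest fold in each library, a comparison chosen after the results were seen, the balance turned, and of 1176 such windows 256 held more untreated-specific and 873 more PMA-specific regions, at least 2 times as many in 626. That cut removed almost only untreated islands, so part of the turn was built in. After chr5:73000001-74000000, the windows with most PMA-specific regions were chr13:34000001-35000000 (27 against 29 untreated-specific), chr5:148000001-149000000 (27 against 12), chr13:44000001-45000000 (26 against 35) and chr8:134000001-135000000 (26 against 12). Windows with 24 PMA-specific regions were chr1:218000001-219000000 (31 untreated-specific), chr3:124000001-125000000 (10), chr5:55000001-56000000 (6) and chr9:114000001-115000000 (29). With equal numbers of islands, the windows named after the first held 33 PMA-specific against 6 untreated-specific regions, 34 against 2, 33 against 11 and 38 against 4, in the order given. Those with 24 then held 30 against 9, 33 against 4, 28 against 5 and 28 against 18.

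Fewer regions were listed after PMA. Fewer reads do not account for it, since the PMA libraries were 1.83 times as large relative to the input. Weaker FAIRE enrichment at every region may account for most untreated-specific regions, of which 21.6% would still have passed in both PMA libraries after rescaling by the reads in regions called in all 4. For the PMA-specific regions, 5.59 times as many were detectable in the untreated libraries as the most that a mixed pair of libraries called alone. That is above the limit set for a result that weaker enrichment would not give. Yet the regions were picked for passing in the PMA libraries, and a mixed pair does not hold what both PMA libraries share. The ratio therefore cannot exclude weaker enrichment as a reason for them. Mitochondrial DNA lost excess fold to a like degree, with a PMA to untreated ratio of 0.493 beside 0.464 in regions called in all 4. A weaker recovery of nucleosome-free DNA as a whole could give this. However, duplicates had been removed, which caps the reads that 16500 bp can hold. Mitochondrial reads numbered 17702 and 17900 in the untreated and 19359 and 19739 in the larger PMA libraries. The fold could thus fall with library size alone, which was not tested. The amount of mitochondrial DNA per cell was not measured apart from the mixed input either. Whether the loss came from the cells or from the extraction therefore stays open.

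Untreated-specific regions were 4.54 times as often within 5 Mb of a chromosome end as PMA-specific regions. Differences in input read density do not account for all of it, since the ratio was at least 2.23 in each of 5 classes of that density. A gained segment in only 1 condition was not tested by this, since the input was a mixture of both. Weak calls are not the whole reason either: the ratio was 2.47 among regions with a fold of at least 4 in both libraries, though this is lower than over all regions. The longer lists of the untreated libraries may be part of the reason: with the 72342 islands of highest fold in each library the ratio fell to 1.77 (95% interval over resampled chromosomes 1.46 to 2.18). By the limit of 1.5 set for this test the result is undecided, since the interval reaches below it. The interval nevertheless lies above equal shares, and the share was higher for untreated-specific regions on 21 of 23 chromosomes at this cut. These values argue against list length as the whole reason. A dependence of recovery on GC content cannot be told apart from a change in the cells, because no genome sequence of the build was used here. An effect of PMA on these parts of the chromosomes remains an untested hypothesis.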
